A study of Taeniopygia guttata with 170 samples.

How the data were processed

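RNA from Area X, HVC, RA and LMAN of adult male zebra finches was measured on 170 one-colour custom songbird arrays. Per the labels' protocols the birds were kept alone overnight, brains were taken either in the morning before singing or right after a period of singing with more than 25 song bouts per 0.5 h, RNA was purified with Picopure columns and amplified from total RNA as cDNA with the WT-Ovation Pico system, and the product was labelled with Cy3. The labels' protocols give 54 birds for the 170 arrays, so the regions come from shared birds, and they name 4 to 6 independent experiments per time. Region, singing time and replicate letter were taken from the sample labels, which gave 35 groups.

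The deposited scanner files hold intensity values. Per the file headers they are Feature Extraction output (protocol GE1-v5_95_Feb07) of a GenePix 4000B scan, with a processed signal that is background-subtracted and detrended within each array and not normalized between arrays, next to raw spot and local background signals. Flags of 0 or 1 for saturation, uneven spots, outlying spots and spots well above background were set by the same software, per the file headers. The deposited series table holds log2 values made by the authors, whose array medians run from 8.11 to 8.56 and whose rank correlation with the median spot signal is 0.9999 or higher on every array. Whether the authors normalized them between arrays is not given in the sources used here. Each array had 44969 spots, of which 43552 were not controls and represented 43125 probes. Between 3 and 93 spots per array were saturated. Of the entries of the series table, 1417 matched no such probe and were not used here.

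Spots flagged as uneven or outlying were left out (327 values of 254 probes), and the spots of a probe were averaged. The main value was the log2 of the processed signal minus the 75th percentile of the array's log2 values. A probe was tested where it was well above background on at least 50% of the arrays of at least 1 group of the fit. The share of probes well above background had a median of 65.1% on silent arrays (50.5% to 88.4%) and 63.2% on singing arrays (36.7% to 98.7%). The planned unit was the gene. Only 148 probes, under 135 names, could be given a gene name from the probe labels and a RefSeq gene table of a zebra finch assembly, and of 110 accession-like labels 7 matched that table. Counts are therefore counts of probes, and the other 42977 probes are reported by number only, apart from 2 examples. A named gene is represented by its brightest probe. Many labels are spelled as mouse gene symbols, such as Cd59a and Olfr1388, and that of LARP5 names the chicken gene. Whether such probes match the zebra finch gene was not tested, so these names are those of the labels. ER81 and ETV1 are names of 1 gene and are counted separately in the numbers of named genes.

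In each region a linear model with 1 mean per singing time and 1 for silent birds was fitted with limma 3.58.1 (statmod 1.5.0) in R 4.3.3, using lmFit and eBayes, and p-values were adjusted over all probes tested (Benjamini and Hochberg). A probe was called at an adjusted p under 0.05. Early (0.5 and 1 h), middle (2 to 4 h) and late (5 to 7 h) singing were each compared with silence. Late and early singing were compared among singing birds with batch code as a fixed block. In silent birds each region was compared with the mean of the other 3, with the replicate letter as a fixed block. Moderated F tests asked whether the early response (0.5 and 1 h) and the late response (5 and 6 h) differed between regions, with time and letter together as the block. The fits, groupings, gene lists and other settings were chosen before the data were examined. All p-values measure the spread between these samples.

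Letters were checked as pairs by correlating the deviations of arrays from their group means. In silent birds, 32 same-letter pairs from different regions had a median correlation of 0.44 (lowest 0.26), against -0.07 for 123 pairs of different letters, and the letter was used as a block there. Each silent letter carried the same batch code in every region, so the same-letter pairs alone do not separate the bird from the batch. But letters d, e and f also shared a code, as did h and i, so many pairs of different letters shared a code too. Of the 123 pairs of different letters 11.4% were above 0.1, against 100% of the 32 same-letter pairs. This argues against batch code as the whole source of the same-letter correlation, although the 123 pairs were not split by code. Time and letter together give 55 combinations against 54 birds, so the letter does not mark the birds exactly. In singing birds, 138 same-letter pairs from different regions on the same array design had a median of 0.33 (lowest -0.15), and 23 pairs across designs 0.13 (lowest -0.57), so the planned block of time and letter in the F tests is less certain. Between singing times within a region the same-letter median was 0.04 in Area X, 0.25 in HVC, 0.21 in RA and -0.01 in LMAN, against -0.01, -0.08, -0.04 and 0.00 for other letters, and not every pair was above 0. The letter goes partly with the batch code, and it was not used as a block there except as an alternative. Batch codes, read from the sample descriptions, hold silent or singing arrays but never both, so batch could not be a fixed term in the comparison with silence. It was used as a random block instead (limma's duplicateCorrelation on 3000 probes), with estimated correlations of 0.21 in Area X, 0.38 in HVC, 0.32 in RA and 0.29 in LMAN.

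In each comparison the called named genes with the 8 highest and 8 lowest log2 differences were selected for the text, or the 16 with the lowest p in the F tests. Added to these were EGR1, FOS, ARC, DUSP1, BDNF, HSPA5, PER2 and FOXP2 whatever their result, and up to 4 called members of each gene list. Of those 8 genes only EGR1 has a name on this array. Other genes are mentioned for comparison only. Of 24 gene lists, the immediate early, circadian, oxidative phosphorylation, proteasome, axon guidance, steroid, striatal and pallial excitatory lists had at least 1 member tested. The lists for activity-dependent effectors, endoplasmic reticulum chaperones, cholesterol synthesis and potassium channels had a named member that was never bright enough. The other 12, with the markers of glia, vessels and inhibitory neurons among them, had no member named on the array. The planned competitive list test (camera) was not run, since the lists hold too few named members, and members are counted instead. A gene below background on all arrays of a group is given as a lower bound on the fold, which replaces its values there by the lowest signal well above background on each array.

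Other settings planned beforehand were normexp background correction (offset 50), quantile normalization, the authors' table, no filter or a stricter filter on dim probes, array weights, batch code or scan date as a random block, the replicate letter as a block or no such block, no batch block, the largest batch alone, each of the other 3 regions singly, and leaving out each library in turn. Array design as a fixed block, arrays of the later design alone, scan date as a fixed block and batch code in place of the bird block were added after the data were examined. The mean of all probes of a gene was planned and not run, since most probes carry no name. A count was taken as moved when it changed by more than 1.5 times. For each comparison the samples were also regrouped in 100 random splits. The fits were tested on simulated data with 200 changed probes: for early Area X, 53 of 66 changes of log2 2, 18 of 67 of log2 1 and 4 of 67 of log2 0.5 were recovered, and for late against early LMAN, 19 of 63 changes of log2 2 and 0 of 67 of log2 1. The simulated values had no background floor and, in the comparisons with silence, no batch effect, so they do not show how batch affects the calls. Files were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, rank correlations were taken with scipy 1.17.1 and figures drawn with matplotlib 3.10.9.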

Results

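Gene expression was measured in 4 song nuclei of adult male zebra finches. Area X is the striatal nucleus of the song system, HVC and RA are the pallial nuclei of the vocal motor pathway, and LMAN is the pallial nucleus that projects to RA and Area X. Birds spent the night alone, and brains were taken either in the morning before any singing (silent) or directly after 0.5 h or 1 to 7 h of singing. The 170 one-colour arrays comprised 50 of Area X, 45 of HVC, 49 of RA and 26 of LMAN. Silent birds gave 6, 6, 7 and 5 of these arrays, and each singing time gave 4 to 6 arrays in the first 3 regions and 3 arrays in LMAN, where 7 h was not analysed here. Singing times were grouped into an early phase (0.5 and 1 h), a middle phase (2, 3 and 4 h) and a late phase (5, 6 and 7 h, in LMAN 5 and 6 h). On the silent arrays a median of 65.1% of probes were well above background (n = 24), against 63.2% on the singing arrays (n = 146). The number of arrays limits the precision of all comparisons. The arrays carried 12 batch codes, each of which held either silent or singing arrays, so singing and silent birds could not be compared within a batch. Since silent brains were taken in the morning, the middle and late comparisons with silence do not separate singing from the time of day either. Batch code accounted for 80.1% of the variation between arrays along the first principal component, array design for 53.3%, region for 32.7% and singing against silence for 8.34%. These shares overlap and are not a ranking. Each batch code held only silent or only singing arrays, and some held 1 region alone, so the share of batch code takes in that of singing and part of that of region.

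The title of the series asks which singing-driven changes are common to the song nuclei and which are enriched in 1 of them. Singing and silent birds were compared first. In Area X, EGR1 rose early in singing. EGR1, called ZENK in songbirds, is a zinc-finger transcription factor that neurons switch on when active. Its log2 level went from 1.82 ± 0.66 (SD, n = 6) in silent birds to 4.02 ± 0.67 (SD, n = 10), a difference of 2.20 ± 0.39 (SE, adjusted p = 0.000818), and it was above the silent mean in 10 of 10 singing arrays. The highest group mean was at 0.5 h, at 4.47 ± 0.58 (SD, n = 5). The 12 EGR1 probes all passed, with log2 differences of 1.74 to 2.71. LARP5, an RNA-binding protein of the La-related family whose probe is labelled as the chicken gene, rose by 1.30 ± 0.22 (SE, adjusted p = 0.000353, higher in 10 of 10 arrays). HIST2H2BE, a histone H2B gene, was lower (adjusted p = 0.0477, 10 of 10 arrays), but it was well above background on 3 of 6 silent and 1 of 10 singing arrays, so no fold is given, and its call ended in 10 of 13 refits without 1 library. In total 1478 of 34633 probes differed, 1034 higher and 444 lower, by limma's test. With batch code as a random block 73 probes passed, among them EGR1 (2.40, adjusted p = 0.00529) and LARP5 (1.21, adjusted p = 0.0297). On arrays of the later design alone limma called 0 probes, with 1874 at an unadjusted p under 0.05, and EGR1 stood at 1.94 (adjusted p = 0.691). Leaving out 1 library moved the count by more than 1.5 times in 14 of 16 refits, from 399 without silent f to 3357 without 0.5 h c.

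**Figure D1:**
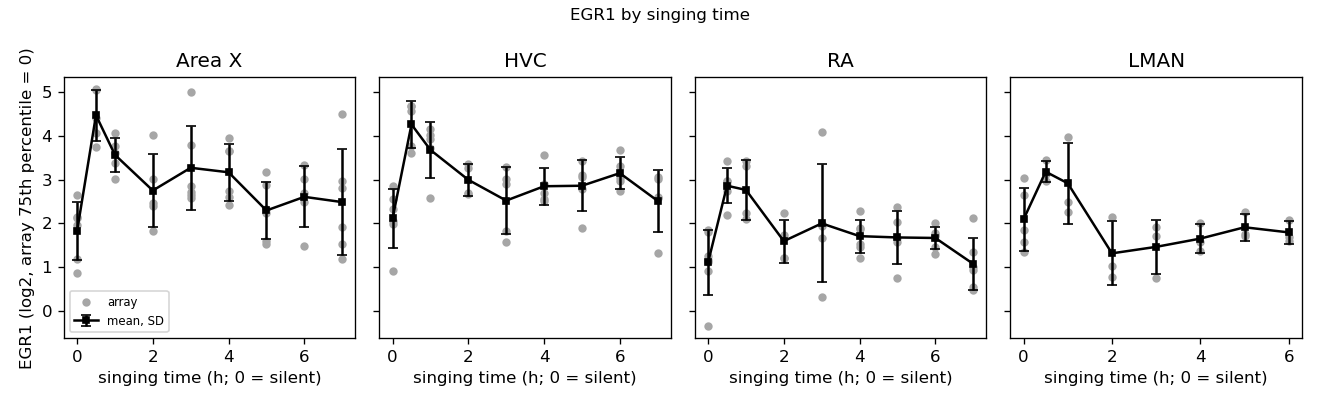
EGR1 log2 level (each array's 75th percentile = 0) against hours of singing, with silent birds at 0 h, in the 4 regions. Circles are single arrays, squares group means and bars SD; in Area X the mean went from 1.82 in silent birds to 4.47 at 0.5 h and was 2.49 at 7 h.

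D1A, GPM6A, ESR1 and SCAMP1 passed in Area X in the middle or late phase and not in the early phase. Some group means had moved at 0.5 and 1 h already. D1A went from 2.75 in silent birds to 3.50 and 3.42, GPM6A from -0.32 to -1.22 and -1.51, and SCAMP1 from 1.62 to 1.14 and 1.16. ESR1 went from -1.78 to -2.64 and -1.91. A later onset is therefore not shown. D1A, a dopamine receptor that raises cyclic AMP and marks striatal neurons, rose in the middle phase by 0.68 ± 0.22 (SE, adjusted p = 0.0278) and in the late phase by 0.93 ± 0.22 (adjusted p = 0.00396), and it was higher in 17 of 17 arrays in each. GPM6A, a membrane glycoprotein of neurons that takes part in neurite outgrowth, fell by 1.48 ± 0.42 in the middle phase (adjusted p = 0.0122, lower in 17 of 17 arrays) and by 1.50 ± 0.42 in the late phase (adjusted p = 0.011, lower in 16 of 17). ESR1, the alpha oestrogen receptor, fell by 0.86 ± 0.26 in the late phase (adjusted p = 0.0171, lower in 17 of 17 arrays). SCAMP1, a protein of secretory carrier membranes, fell by 0.46 ± 0.15 and 0.49 ± 0.15 (adjusted p = 0.033 and 0.0202, lower in 16 of 17 arrays in each phase). LARP5 was higher by 1.19 ± 0.20 and 1.11 ± 0.20 (adjusted p = 0.000179 and 0.000365, 17 of 17 arrays in each). EGR1 was still higher in the middle phase, by 1.24 ± 0.36 (adjusted p = 0.0154, 17 of 17 arrays), and differed by 0.64 ± 0.36 in the late phase, which did not pass (adjusted p = 0.214, higher in 12 of 17). Of the 12 EGR1 probes 11 passed in the middle phase (1.04 to 1.93) and 4 in the late phase (0.31 to 1.39), so whether EGR1 was called late depended on the probe.

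A group of mostly weakly expressed genes was also higher in Area X in the middle and late phases. Most of their probes carry labels spelled as mouse gene symbols, and whether they match the zebra finch genes was not tested. Their group means were above silent at 0.5 and 1 h already, as for JPH4 (-2.34 in silent birds, then -0.33 and -0.38). A later onset is therefore not shown. CD59A, a complement inhibitor, rose by 2.51 ± 0.57 in each phase (adjusted p = 0.00295 and 0.00303, higher in 15 and 16 of 17 arrays), and JPH4, a junctophilin that ties the plasma membrane to the endoplasmic reticulum, by 2.31 ± 0.73 and 2.38 ± 0.73 (adjusted p = 0.0238 and 0.0193, 15 and 14 of 17 arrays). GGN (2.23 ± 0.62 and 2.32 ± 0.62), the dicarboxylate transporter SLC13A3 (1.97 ± 0.53 and 1.94 ± 0.53) and the transcription factor POU2F1 (1.04 ± 0.35 and 1.00 ± 0.35) passed in both phases. The interferon-induced gene OASL was higher by 2.15 ± 0.69 and 1.92 ± 0.69 (adjusted p = 0.0264 and 0.044). AARD (adjusted p = 0.00634 and 0.0168), OLFR1388 (0.00683 and 0.0114) and ABCA6 of the lipid transporter family (0.0206 and 0.0155) were higher in both phases. The carboxylesterase CES2 (adjusted p = 0.0234) and BARD1, the partner of the repair protein BRCA1 (adjusted p = 0.0348), were higher in the late phase. These 5 genes were well above background on 1 of the 6 silent arrays, so no fold is given. HIST2H2BE was lower in both phases (adjusted p = 0.0096 and 0.017), where it was well above background on 1 and 3 of 17 arrays. The mitotic motor KIF20A fell by 1.10 ± 0.39 in the middle phase, a size that is uncertain. It was well above background on 1 of 5 arrays at 2 h, 1 of 6 at 3 h and 2 of 6 at 4 h. Apart from JPH4, the other genes of this group were well above background on 2 or 3 of the 6 silent arrays, so their differences are imprecise. In LMAN most of the higher genes also differed between 3 h and 4 h, whose arrays carried different batch codes. JPH4 was at 0.05 and -3.17, OASL at -1.68 and -4.09 and CD59A at -2.63 and -5.81. CD59A was well above background on 0 of 3 arrays at each of these times, so its values there are not levels of expression. POU2F1 went the other way (-2.52 and -1.93). On the 3 h arrays 43.7% to 50.7% of probes were well above background, against 64.8% to 69.6% at 4 h. ABCA6 (-3.91 and -6.08) and BARD1 (-4.02 and -5.70), well above background on 0 of 3 arrays at both times, also stood higher at 3 h. The background level therefore differed between these arrays as well, and how much of the differences it made was not tested. Time and batch cannot be told apart there. With normexp background correction KIF20A turned to 0.06 (adjusted p = 0.856) and HIST2H2BE was lost (adjusted p = 0.759 and 0.814).

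In the middle phase 5948 of 34633 probes differed from silent Area X (4160 higher, 1788 lower), and in the late phase 6484 (4449 higher, 2035 lower). With the authors' values the split turned, at 374 higher and 476 lower early, 3075 and 3228 in the middle phase and 2711 and 3150 late. With batch code as a random block 239 and 249 passed. Of the genes above, LARP5 kept its call there, in the middle phase (1.09, adjusted p = 0.0309). D1A late was at 0.78 (adjusted p = 0.14), GPM6A late at -1.46 (adjusted p = 0.204), ESR1 late at -0.65 (adjusted p = 0.366) and EGR1 in the middle phase at 1.37 (adjusted p = 0.141). With scan date as a fixed block 4, 7 and 585 probes passed in the 3 phases, and D1A was at 0.05 ± 0.31 in the middle phase and 0.05 ± 0.37 late (SE, adjusted p = 0.979 and 0.969), so that its rise was not seen in that fit. There SCAMP1 was at -0.06 and -0.21 (adjusted p = 0.976 and 0.855), ESR1 late at -0.44 (adjusted p = 0.821), EGR1 in the middle phase at 0.83 (adjusted p = 0.735), GPM6A late at -2.64 (adjusted p = 0.197) and LARP5 late at 0.83 (adjusted p = 0.343). Of the weakly expressed genes AARD (adjusted p = 0.0372) and ABCA6 (adjusted p = 0.0159) passed there late. ESR1 was also lost with normexp (-0.24, adjusted p = 0.392). Single silent libraries decided several calls. EGR1 in the middle phase was lost without silent e (1.05, adjusted p = 0.0611) or f (1.11, adjusted p = 0.0513). D1A in the middle phase was lost without silent d (0.57, adjusted p = 0.0969), f (0.64, adjusted p = 0.0687) or h (0.64, adjusted p = 0.0662), and ESR1 without silent d (-0.76, adjusted p = 0.0579) or i (-0.73, adjusted p = 0.0655). SCAMP1 was lost without silent d, e or f in both phases and without h in the middle phase (-0.46 to -0.42), and the late count fell to 4252 without silent h. Among the weakly expressed genes, POU2F1 was lost in 8 and 10 of 23 refits (0.90 to 1.05 and 0.88 to 1.02), KIF20A in 12 (-1.09 to -0.98), BARD1 in 4, OASL in 3, JPH4 in 3 and 1, ABCA6 in 2 and 2, AARD late in 2, CES2 in 2 and OLFR1388 late in 1. For OASL, JPH4, ABCA6, AARD, CES2 and OLFR1388 the library left out was a silent one each time. D1A, GPM6A, LARP5, CD59A, GGN and SLC13A3 in the late phase kept their calls in all 23 refits.

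In HVC, EGR1 rose early in singing, from 2.11 ± 0.67 (SD, n = 6) to 3.97 ± 0.63 (SD, n = 10). The difference was 1.86 ± 0.30 (SE, adjusted p = 0.00035, higher in 10 of 10 arrays), and 12 of 12 EGR1 probes passed. It was 0.68 ± 0.28 in the middle phase (adjusted p = 0.396, higher in 12 of 14 arrays) and 0.73 ± 0.28 in the late phase (adjusted p = 0.229, 13 of 15), which did not pass. Of the 46 named genes tested EGR1 was the only one to pass in any phase, and at an unadjusted p under 0.05 there were 2, 3 and 7 in the 3 phases. Of 33871 probes limma called 73 early (71 higher, 2 lower), 88 in the middle phase (75 higher, 13 lower) and 281 late (184 higher, 97 lower). With batch code as a random block these became 24, 0 (1019 at an unadjusted p under 0.05) and 10. EGR1 early passed in that fit (2.11, adjusted p = 0.0351) and on the later array design alone (1.71, adjusted p = 0.0148). Without silent h the middle count was 48 and the late count 129.

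In RA, EGR1 rose early from 1.11 ± 0.73 (SD, n = 7) to 2.82 ± 0.50 (SD, n = 10), by 1.70 ± 0.33 (SE, adjusted p = 0.00633, higher in 10 of 10 arrays), and 11 of 12 EGR1 probes passed. It was 0.66 ± 0.30 in the middle phase (adjusted p = 0.576, 14 of 15 arrays) and 0.37 ± 0.30 in the late phase (adjusted p = 0.57, 12 of 17). D1A differed by 1.00 ± 0.41, 1.03 ± 0.38 and 0.84 ± 0.37 in the 3 phases and did not pass (adjusted p = 0.735, 0.402 and 0.276). EGR1 was the only 1 of 41 named genes called. Of 33472 probes, 38 passed early (36 higher, 2 lower), 73 in the middle phase (62 higher, 11 lower) and 243 late (171 higher, 72 lower). With the authors' values more probes were lower late in RA, 128 against 34 higher, and in the middle phase 19 were higher and 11 lower. With scan date as a fixed block 1938, 4335 and 4433 passed in the 3 phases, and the splits turned to 424 higher and 1514 lower, 1169 and 3166, and 1215 and 3218, with medians of all probes of -0.39, -0.31 and -0.27. With batch code as a random block limma called 0 probes early (752 at an unadjusted p under 0.05), 5 in the middle phase and 8 late, and EGR1 early was at 1.79 (adjusted p = 0.333). EGR1 early was also lost without silent c (1.46, adjusted p = 0.0562) and on the later array design alone (1.66, adjusted p = 0.244). Without silent h the middle count was 29 and the late count 119.

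In LMAN, EGR1 was 0.95 ± 0.34 above silent early in singing, at 3.05 ± 0.62 (SD, n = 6) against 2.10 ± 0.72 (SD, n = 5), which did not pass (adjusted p = 0.258, higher in 6 of 6 arrays). It was at -0.62 ± 0.32 in the middle phase (adjusted p = 0.298, lower in 8 of 9) and at -0.24 ± 0.34 in the late phase (adjusted p = 0.784, lower in 5 of 6). The 12 EGR1 probes ran from 0.94 to 1.62 early, from -0.62 to -0.09 in the middle phase and from -0.59 to -0.04 late, so the probe used here was at the lower end in the middle phase. The transcription factor gene KLF6 passed in the middle phase (adjusted p = 0.0492), but it was well above background on 0 of 5 silent and 2 of 9 middle arrays, so no fold is given, and its call ended in 12 of 14 refits. No other named gene passed in LMAN, with 9, 12 and 6 of 44 at an unadjusted p under 0.05. Of 32746 probes, limma called 78 early (72 higher, 6 lower), 861 in the middle phase (592 higher, 269 lower) and 366 late (185 higher, 181 lower), and 0 (1255 at an unadjusted p under 0.05), 9 and 9 with batch code as a random block. With the authors' values the split turned in the middle phase, to 195 higher and 388 lower, and was 85 and 314 late. The counts rested on single libraries. Early they ran from 9 without 0.5 h e to 495 without 0.5 h f, in the middle phase from 154 without silent f to 1782 without 2 h f, and late from 73 without silent f to 673 without 5 h d.

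**Figure D2:**
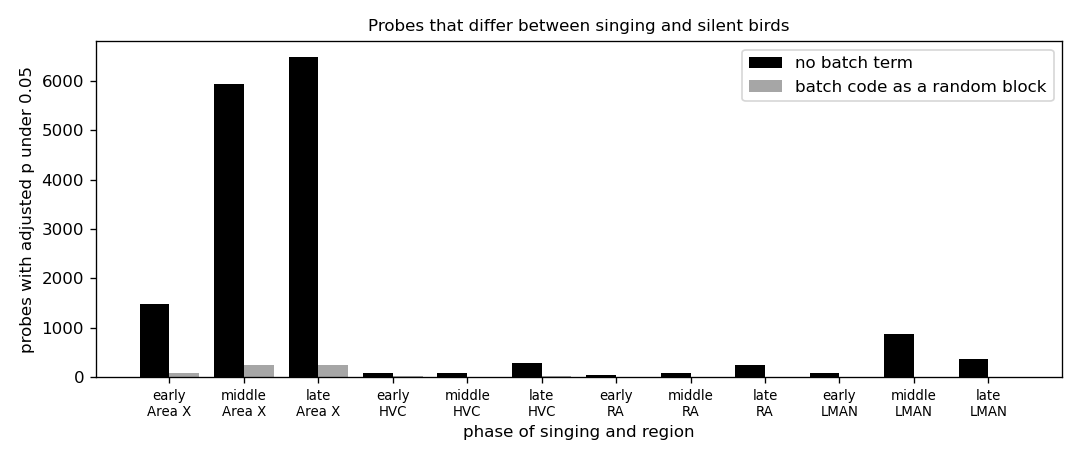
Number of probes called in each phase against silent birds in the 4 regions (vertical axis, probes), as bars without a batch term and with batch code as a random block. The late Area X count went from 6484 to 249 and the early RA count from 38 to 0.

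Whether the response to singing differed between the regions was tested with time and letter as a block. Many singing arrays carried batch codes used for 1 region only, while the regions shared the codes of the silent arrays, so differences in response between regions are confounded with batch. By the moderated F tests the EGR1 response was not shown to differ between regions over all probes, early (adjusted p = 0.894) or late (adjusted p = 0.439). Its unadjusted p was 0.0226 early and 0.0388 late, so equal responses are not shown either. Of 36741 probes, 14 differed early (1883 at an unadjusted p under 0.05) and 148 late (3887), none of them among the 63 named genes, of which 4 and 8 reached an unadjusted p under 0.05. Without Area X silent f the counts were 5 and 69, and without RA 1 h d the early count was 28. They were 2 and 19 without the bird block and 1 and 63 with batch code in its place, and the late count was 3837 on the later array design alone. EGR1 passed with array weights (adjusted p = 0.00548 early and 0.0418 late), the only setting run in which it did.

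Probes called higher early were shared between regions. In Area X, HVC and RA together 32 probes were called higher, against 0.00228 for independent lists, and 11 of the 32 were EGR1 probes. Of the others none carried a gene name here. The unnamed probe 0203P0023N11 rose by 2.77, 3.28 and 3.43 in Area X, HVC and RA (adjusted p = 0.0085, 1.08e-05 and 0.00119), and 0202P0013C15 by 2.17, 2.48 and 2.99 (adjusted p = 1.3e-05, 2.05e-07 and 0.00025). HVC and RA shared 32 such probes (0.0769 for independent lists), HVC and LMAN 8 (0.149), and all 4 regions 4. Same-lettered silent arrays of different regions deviated together, and the regions share batch codes, so the lists are not independent. The overlap needs the 38 early RA calls. In early RA limma called 0 probes with batch code (752 at an unadjusted p under 0.05) or scan date (1606) as a random block and on the later array design alone (1854), and 3 with the replicate block, so there was no overlap of 32 probes under these settings.

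Late and early singing were then compared within the singing birds, with batch code as a fixed block. EGR1 fell in Area X by 1.73 ± 0.29 (SE, adjusted p = 0.000529, lower in 16 of 17 late arrays), in HVC by 1.38 ± 0.26 (adjusted p = 0.00197, 15 of 15) and in RA by 1.27 ± 0.21 (adjusted p = 0.000578, 17 of 17), and in each of these regions 12 of 12 EGR1 probes passed. In LMAN the difference was -1.55 ± 0.42 (adjusted p = 0.171, lower in 6 of 6). NKX2.2, a homeobox factor of the oligodendrocyte lineage, fell by 0.81 ± 0.19 in HVC (adjusted p = 0.00823, lower in 12 of 15), and no other named gene passed. A total of 45 probes were lower in Area X, HVC and RA alike, 12 of them EGR1 probes, against 0.0426 for independent lists. Within the largest batch EGR1 differed by -1.93 (adjusted p = 0.0338) in Area X, -1.31 (adjusted p = 0.0548) in HVC and -1.23 (adjusted p = 0.0507) in RA. In LMAN, where the largest batch held a single late array, it differed by -1.34. The Area X call was lost with scan date as a random block beside batch code (-1.42, adjusted p = 0.221), the HVC and RA calls on the later array design alone (-1.45, adjusted p = 0.442, and -1.23, adjusted p = 0.126), and NKX2.2 was lost without the batch block (-0.64, adjusted p = 0.171) and within the largest batch (-0.81, adjusted p = 0.0689). In total 535 of 33558 probes differed in Area X (293 higher, 242 lower), 2739 of 33518 in HVC (1597 higher, 1142 lower), 349 of 33350 in RA (188 higher, 161 lower) and 5 of 32499 in LMAN (4 higher, 1 lower). The HVC and RA counts fell by more than 1.5 times without the batch block and on the later array design alone. With scan date as a random block beside batch code the Area X, HVC and RA counts did so too. Within the largest batch the counts were 132 in Area X, 651 in HVC and 101 in RA, with the split turned in HVC (349 lower) and RA (20 higher, 81 lower). No count is used here for LMAN, whose largest batch held a single late array. The authors' values also turned it in RA (100 and 415) and LMAN (5 and 332), so no direction is read from these splits. Without 1 library they fell as far as 307 in Area X (without 1 h a), 1632 in HVC (without 7 h b), 177 in RA (without 1 h d) and 0 in LMAN by limma (without 5 h d, with 3116 at an unadjusted p under 0.05), and in LMAN rose to 27 without 6 h d. The time of day at sampling is not given for single birds, and the design does not separate it from singing time.

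Each region was compared with the other 3 in silent birds, with the replicate letter, taken to mark the bird, as a block (the bird block). Time and letter together give 55 combinations against the 54 birds of the labels, so the letter does not mark the birds exactly. Area X stood apart by its dopamine receptors. D1A was 3.38 ± 0.27 above the other regions (SE, adjusted p = 8.71e-08, 6 of 6 arrays). D1B was well above background on 0 of 6 HVC, 1 of 7 RA and 0 of 5 LMAN arrays, and it was at least 5.74-fold higher in Area X than in HVC and at least 5.22-fold higher than in LMAN (adjusted p = 4.15e-06 and 4.75e-06). D2, the receptor that lowers cyclic AMP, was at least 2.44-fold, 2.55-fold and 2.32-fold higher in Area X than in HVC, RA and LMAN (adjusted p = 0.00859, 0.00314 and 0.0203), and the D2 difference from the other 3 together was lost with normexp (adjusted p = 0.0825). GNAI1, an inhibitory G-protein subunit, was 1.83 ± 0.16 higher (adjusted p = 2.27e-07, 6 of 6). YWHAH, a 14-3-3 protein, was lower by a log2 difference of -1.24 ± 0.10 (adjusted p = 7.82e-08), and the ETS-family transcription factor ETV1, also called ER81, by its probe labelled ER81 (-1.36 ± 0.14, adjusted p = 1.97e-06) and its probe labelled ETV1 (-0.89 ± 0.22, adjusted p = 0.0047; not against each other region singly), the membrane ligand EFNB2 (-1.07 ± 0.19, adjusted p = 0.000283) and the neuronal RNA-binding protein ELAVL4 (-0.36 ± 0.07, adjusted p = 0.00119) were lower, each in 6 of 6 arrays. GPM6A was lower too (-0.62 ± 0.11, adjusted p = 0.000271, 5 of 6), but not without the bird block (-0.54, adjusted p = 0.244). KIF20A (1.39) and the histone genes HIST2H3C1 (0.80), HIST2H2BE (0.54) and HIST1H4H (0.49) passed as well, KIF20A being well above background on 3 of 6 Area X and 5 of 18 other arrays and HIST2H2BE on 3 of 6 and 6 of 18. D1D-like passed (adjusted p = 0.00213) but was well above background on 3 of 6 Area X and 2 of 18 other arrays, so no fold is given. With normexp D1D-like, KIF20A and HIST2H2BE were lost, the last at -0.01 (adjusted p = 0.963), and HIST2H3C1 was lost without the bird block (0.80, adjusted p = 0.0736). HIST2H2BE was also lost in 4 of 21 refits (0.40 to 0.58), among them that without Area X silent d (0.40, adjusted p = 0.134), and HIST1H4H in 10 of 24 refits (0.35 to 0.49).

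**Figure D3:**
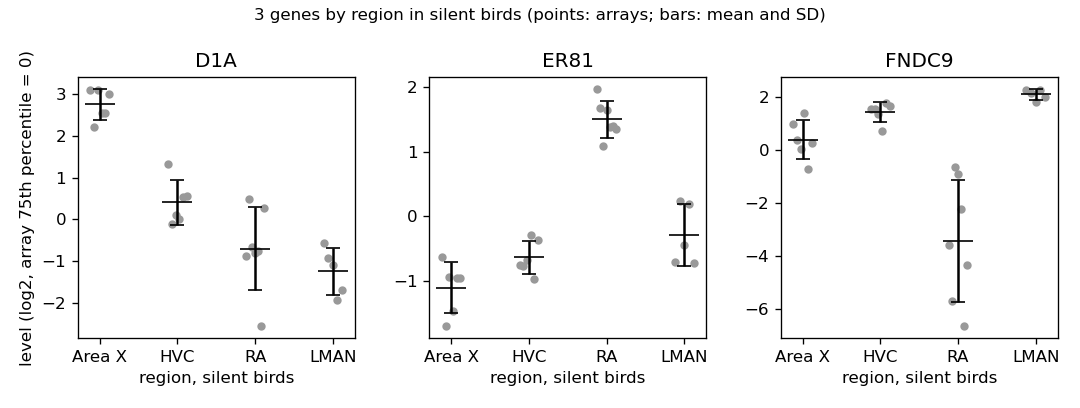
D1A, ER81 (ETV1) and FNDC9 log2 levels (each array's 75th percentile = 0) by region in silent birds. Points are arrays, with means and SD; D1A was highest in Area X (2.75 ± 0.37, n = 6), ER81 in RA (1.50 ± 0.29, n = 7), and FNDC9 lowest in RA (-3.43 ± 2.31, n = 7).

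RA was marked by the gene ETV1. Its probe labelled ER81 was 2.13 ± 0.14 (SE, adjusted p = 7.12e-08) and its probe labelled ETV1 2.08 ± 0.21 (adjusted p = 6.09e-06) above the other regions, each in 7 of 7 arrays. ATP1B1, the beta subunit of the sodium pump, was 0.45 ± 0.12 higher (adjusted p = 0.0125, 7 of 7). FNDC9, a protein with a fibronectin type III domain, was lower by a log2 difference of -4.65 ± 0.57 (adjusted p = 3.48e-05, 7 of 7), with 3 of 7 RA arrays above background. D1A (-1.47 ± 0.25, adjusted p = 0.000539), GNAI1 (-0.65 ± 0.15, adjusted p = 0.00494), ESR1 (-1.16 ± 0.30, adjusted p = 0.0102), the SLIT receptor ROBO2 (-1.02 ± 0.27, adjusted p = 0.0105), the ephrin Ephrin-A5 (-1.57 ± 0.43, adjusted p = 0.0141) and EGR1 (-0.77 ± 0.22, adjusted p = 0.0208) were lower in RA, in 7, 7, 6, 7, 6 and 7 of 7 arrays. Against each other region singly ER81, ETV1 and FNDC9 passed, and these 6 genes and ATP1B1 did not. D1A and GNAI1 were lower in RA than in the mean that includes Area X, where they stood at 2.75 and 0.96. D1A was at -0.70 in RA and -1.25 in LMAN, and GNAI1 at -0.93 in RA and -0.88 in LMAN. ESR1 and ROBO2 were lost with normexp (-0.36, adjusted p = 0.119, and -0.29, adjusted p = 0.18). ATP1B1 was lost without the bird block (0.41, adjusted p = 0.163), and so was EGR1 (-0.90, adjusted p = 0.0591), which was lost also without RA silent h (-0.70, adjusted p = 0.0604) or i (-0.66, adjusted p = 0.0751).

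In HVC and LMAN, none of the genes named here passed against each of the other 3 regions singly, so their differences are from the mean of the other 3. Above that mean in HVC were YWHAH (0.52 ± 0.10, adjusted p = 0.00223, 6 of 6 arrays), GPM6A (0.55 ± 0.11, adjusted p = 0.00346, 5 of 6), ROBO2 (0.99 ± 0.28, adjusted p = 0.0328, 6 of 6) and EFNB2 (0.63 ± 0.19, adjusted p = 0.0419, 6 of 6). ER81 (-0.62 ± 0.14, adjusted p = 0.0104), the guidance ligand SLIT3 (-1.55 ± 0.41, adjusted p = 0.0232) and GNAI1 (-0.52 ± 0.16, adjusted p = 0.046) were below it, each in 6 of 6 arrays, SLIT3 being well above background on 2 of 6. For GNAI1 and YWHAH the difference came from Area X in the mean of the other 3. The GNAI1 means were -0.80 in HVC, -0.93 in RA, -0.88 in LMAN and 0.96 in Area X, and the YWHAH means 3.12, 2.95, 3.08 and 1.84. ER81 was lost without HVC h (-0.50, adjusted p = 0.0564), SLIT3 without HVC e or h (-1.36 and -1.20, adjusted p = 0.087 and 0.111), and ROBO2, EFNB2 and GNAI1 in 5, 16 and 20 of 24 refits, in which their differences were 0.85 to 1.02, 0.54 to 0.69 and -0.60 to -0.46. YWHAH and GPM6A were lost without the bird block (0.50, adjusted p = 0.102, and 0.48, adjusted p = 0.613). Below the mean of the other 3 in LMAN were D1A (-1.91 ± 0.28, adjusted p = 0.000884, 5 of 5 arrays) and GNAI1 (-0.66 ± 0.17, adjusted p = 0.0257, 5 of 5). Above it were YWHAH (0.52 ± 0.10, adjusted p = 0.00527, 5 of 5), FNDC9 (2.53 ± 0.64, adjusted p = 0.0248, 5 of 5) and RORB, an orphan nuclear receptor (1.41 ± 0.38, adjusted p = 0.0361, 5 of 5), RORB being above background on 3 of 5 LMAN arrays. FNDC9 was lost without LMAN e (2.66, adjusted p = 0.0549), h (2.12, adjusted p = 0.125) or i (2.46, adjusted p = 0.0897), RORB in 8 (1.04 to 1.49) and GNAI1 in 5 (-0.68 to -0.64) of 24 refits. Without the bird block YWHAH (0.44, adjusted p = 0.259), GNAI1 (-0.62, adjusted p = 0.0687) and RORB (1.45, adjusted p = 0.131) were lost. D1B also passed as lower in HVC, RA and LMAN, where it was above background on 0 of 6, 1 of 7 and 0 of 5 arrays, so no fold is given.

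Of 32812 probes, 11973 differed between Area X and the other 3 regions (5517 higher, 6456 lower), 3157 for HVC (1893 higher, 1264 lower), 7906 for RA (3818 higher, 4088 lower) and 2187 for LMAN (1226 higher, 961 lower). Without the bird block the counts were 6503, 1103, 3312 and 569, and 4783, 273, 1084 and 147 probes differed from each of the other 3 regions singly. The counts for HVC and LMAN fell to 1800 without HVC i and 982 without LMAN i.

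Among the gene lists fixed beforehand, the striatal list (D1A and D2) had 2 of 2 members higher in silent Area X, and 1 of 2 (D1A) lower in RA and in LMAN than in the other 3 together, Area X included, with the same counts adjusted over the list alone. The list of pallial excitatory neurons came down to 1 gene, entered under its names ER81 and ETV1 with a probe for each. Both probes were higher in RA. Against a mean that includes RA, both were lower in Area X and the ER81 probe was lower in HVC, where both passed adjusted over the list alone, while in LMAN limma called 0 and 1 of the 2 passed adjusted over the list alone. The ER81 means were 1.50 in RA, -0.29 in LMAN, -0.64 in HVC and -1.11 in Area X, and the ETV1 means -0.88, -3.07, -2.89 and -3.22. Of 5 axon guidance genes tested in silent birds, 3 passed in HVC (ROBO2 and EFNB2 higher, SLIT3 lower), 2 in RA (ROBO2 and Ephrin-A5 lower) and 1 in Area X (EFNB2 lower), the same numbers adjusted over the list alone, and limma called 0 in LMAN (1 at an unadjusted p under 0.05). With singing limma called 0 of 5 or 6 axon guidance genes against silent birds in every region and phase, with 1 at an unadjusted p under 0.05 in late HVC, early RA and late RA. In silent birds the steroid list (ESR1) had 1 of 1 lower in RA and the circadian list (RORB) 1 of 1 higher in LMAN. For a list with 1 member tested, the p adjusted over the list alone is the unadjusted p. Passing there means only an unadjusted p under 0.05. On that measure ESR1 passed also in LMAN, RORB also in RA and EGR1 also in HVC. In Area X, the striatal list had 1 of 2 members (D1A) higher in the middle and late phases, and adjusted over the list alone 1 of 2 in each phase, early included. D1A, the list's only member tested outside Area X in singing birds, had an unadjusted p under 0.05 in the 3 phases of RA and in late HVC. It did not pass there adjusted over all probes. Adjusted over the list alone the steroid list's ESR1 also passed in the middle phase of Area X, in late HVC and in early LMAN, and EGR1, the immediate early list's only tested member outside LMAN, also passed in the middle and late phases of HVC and the middle phase of RA. In LMAN 1 of 2 members of that list (EGR1 and KLF6) passed in each phase adjusted over the list alone, and 1 of the 2 pallial probes (ETV1) in the middle phase. The oxidative phosphorylation list (ATP5A1) and the proteasome list (PSMA3) had 0 of 1 called in every comparison in which they were tested, with ATP5A1 passing alone in late HVC and PSMA3 in silent Area X and LMAN. In the comparison of late with early singing, 1 of 1 member of the immediate early list (EGR1) passed in Area X, HVC and RA, and in LMAN 0 of 2 by limma, or 2 of 2 adjusted over the list alone. Of the other lists limma called 0 members there, and adjusted over the list alone 1 of 6 axon guidance genes, ATP5A1 and ESR1 passed in HVC. In the tests of different responses between regions limma called 0 members of any list, with 1 of 2 immediate early genes passing early adjusted over the list alone. Members of the other lists were not tested, because they were not named on the array or were too dim.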

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

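Chosen after the result was seen were the random splits, the later array design alone, scan date as a fixed block, and the use of batch code as a random block, of the largest batch and of the 3 normalizations, themselves planned settings, as tests of an explanation.

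More probes differed from silent birds in Area X (6484 late) than in HVC (281), RA (243) or LMAN (366), but with scan date as a fixed block RA had more (4433 late, 4335 in the middle phase) than Area X (585 and 7), so the ranking depends on the setting. A difference between array batches was weighed first. At matched times the 2 main singing batches of Area X differed in 7403 probes, and those of HVC and RA in 12785 and 15476, although fewer probes differed from silence there. The region with the most calls thus did not have the largest singing batch difference, against the prediction for batch as the source. But the fits against silence have no batch term, so a larger batch difference adds to their error and can lower the calls. The numbers of arrays (39, 23 and 37) and of times (8, 5 and 8) also differed. The comparison therefore cannot decide whether batch made the ranking. Batch code as a random block gave 249 probes late in Area X, with GPM6A at -1.46 ± 0.54 after -1.50 ± 0.42 (SE) and D1A at 0.78 ± 0.25 after 0.93 ± 0.22, and since no batch code holds both silent and singing arrays this fit lowers the number of calls whatever their source. Array design was weighed next: on the later design alone 2343 probes passed in the middle phase of Area X and 4321 late, against 38 and 65 in HVC, 29 and 46 in RA and 861 and 366 in LMAN, whose arrays are all of that design (up to 1782 in its middle phase without 1 library), which argues against design as the source of the ranking there, while early limma called 0 in Area X (1874 at an unadjusted p under 0.05), with 1 singing array at each early time, and 52 in HVC, so design stays open early. For the count against silence, the batches of silent and singing arrays, the time of day and a response to singing cannot be told apart. Silent brains were taken in the morning before singing, and the late ones after hours of singing.

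EGR1 was lower late than early in singing birds. Over 3 normalizations the lowest number of the regions Area X, HVC and RA in which it was called lower was 3, which argues against normalization as the source. Within the largest batch alone the difference was -1.93 ± 0.35 (SE, adjusted p = 0.0338) in Area X, -1.31 ± 0.32 in HVC (adjusted p = 0.0548) and -1.23 ± 0.25 in RA (adjusted p = 0.0507), so the threshold over all probes was missed in HVC and RA with fewer arrays, but each difference lay more than 2 SE below 0, which argues against array batch as the whole source. The Area X call ended with scan date as a random block beside batch code (-1.42 ± 0.39, adjusted p = 0.221, from -1.73 ± 0.29), and the HVC and RA calls ended on the later array design alone, as the errors grew (-1.45 ± 0.67, adjusted p = 0.442, from -1.38 ± 0.26, and -1.23 ± 0.32, adjusted p = 0.126, from -1.27 ± 0.21). The time of day, which is not given for single birds, may contribute and could not be tested.

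Probes called higher early were shared between Area X, HVC and RA, 32 of them against 0.00228 for independent lists. Independent lists would not give so many, but these lists share birds and batches, and 11 of the 32 are EGR1 probes. The comparison therefore cannot decide whether the nuclei share a response. The early RA list behind the overlap held 38 probes, and limma called 0 there with batch code as a random block (752 at an unadjusted p under 0.05). Birds shared between the regions may add to the overlap. Same-letter silent arrays of different regions had a median correlation of 0.44. They also shared a batch code, but so did many pairs of different letters, and 11.4% of the 123 pairs of different letters were above 0.1. Batches may add to it too, since the regions share batch codes of silent arrays, and Area X, HVC and RA also share codes of singing arrays. Neither could be separated from a response common to the 3 nuclei.

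Random splits of the same samples into groups of the same sizes were used to ask how often as many probes are called. Counting the real grouping, 1 of 100 splits called as many in the 3 phases of Area X, in early and late HVC, in early and late RA and in early and middle LMAN, and in late against early singing in Area X, HVC and RA. In middle HVC and RA and late LMAN it was 3 of 100, in the regional comparison of silent birds 1 for Area X and RA and 2 for HVC and LMAN, and in the tests between regions 2 early and 4 late. For late against early singing in LMAN it was 5 of 100, so a chance result was not excluded for these 5 probes. Single splits called 5517 probes in middle HVC (real count 88), 961 in middle RA (73), 1005 in late LMAN (366) and 8624 in silent HVC (3157), so the samples hold structure other than the groups compared. In the comparisons with silence and the tests between regions the splits mixed batch codes, while silent and singing arrays share none. A low number of splits there does not tell a response to singing from a difference between batches.

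The tests of whether the response differs between regions flagged 14 probes early and 148 late, none of them with a gene name. A sample far from the rest of its group was found by Dixon's test in 4 of 84 tests, made on EGR1, D1A and the share of probes above background in each group of 4 to 10 arrays, about the number that a threshold of 1 in 20 gives by chance. EGR1 in HVC at 1 h had a lowest value of 2.57 against 3.72 for the next (gap over range 0.726, n = 5). EGR1 in HVC at 7 h had a lowest value of 1.31 against 2.58 (0.721, n = 5). EGR1 in silent RA had a lowest value of -0.34 against 0.92 (0.573, n = 7). D1A in Area X at 4 h had a highest value of 4.07 against 3.62 (0.683, n = 6).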

How the results depend on the processing

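The settings that use array design, the later design alone, scan date as a fixed block or batch code in place of the bird block are tests chosen after the result was seen; the others were planned. Where a value moved, the cause was not tested unless it is given.

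EGR1 kept its early rise in HVC under every setting run, at 1.69 to 2.14, and in Area X the difference was 1.61 to 2.56, with the call lost on the later design alone (1.94, adjusted p = 0.691) and with scan date as a fixed block (1.61, adjusted p = 0.704). In RA it was 1.47 to 2.79, and the call was lost with batch code as a random block (1.79, adjusted p = 0.333), the replicate block (1.66, adjusted p = 0.104), scan date as a random (1.84, adjusted p = 0.158) or fixed block (2.79, adjusted p = 0.101) and on the later design alone (1.66, adjusted p = 0.244). In the middle phase of Area X it was 0.83 to 1.62, lost with batch code (1.37, adjusted p = 0.141) or scan date (1.14, adjusted p = 0.11) as a random block, on the later design alone (1.26, adjusted p = 0.0983) and with scan date fixed (0.83, adjusted p = 0.735). Late in Area X it passed with array weights (0.79, adjusted p = 0.0432). The late fall against early singing was -1.93 to -1.42 in Area X, -1.61 to -1.12 in HVC and -1.37 to -1.23 in RA. In LMAN it passed with the authors' table (-1.82, adjusted p = 0.0307).

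D1A late in Area X lost its call with batch code (0.78, adjusted p = 0.14) or scan date (0.69, adjusted p = 0.0901) as a random block, on the later design alone (0.62, adjusted p = 0.0699) and with scan date fixed (0.05, adjusted p = 0.969). LARP5 lost its early call on the later design alone (0.97, adjusted p = 0.669) and its late call with batch code as a random block (0.99, adjusted p = 0.059). With the replicate letter as a block, D1A late (0.85, adjusted p = 0.0297), GPM6A late (-2.01, adjusted p = 0.0142) and LARP5 early (1.20, adjusted p = 0.0107) kept their calls, while CD59A (2.23 in each phase, adjusted p = 0.0511 and 0.0541) lost them. In silent birds D1A, D1B, GNAI1, YWHAH, ER81 and EFNB2 kept their calls for Area X against each other region singly, and ER81, ETV1 and FNDC9 for RA.

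With normexp background correction, 79 of 96 named results kept direction and call, 15 lost the call and 2 turned direction: KIF20A in the middle phase of Area X, from -1.10 to 0.0621 (adjusted p = 0.856), and HIST2H2BE in silent Area X, from 0.54 to -0.0081 (adjusted p = 0.963). Both genes lay near background, and why they turned was not tested. Of 22 counts 18 stayed within 1.5 times; early Area X rose from 1478 to 4534, middle HVC went to 56, early LMAN to 25 and middle LMAN to 344. The split of higher and lower probes moved in early Area X from 1034 and 444 to 3997 and 537, in the middle phase from 4160 and 1788 to 6193 and 1529, and in the late phase from 4449 and 2035 to 5971 and 1528. In late RA it went from 171 and 72 to 164 and 31, in late against early RA from 188 and 161 to 218 and 64, and in silent RA from 3818 and 4088 to 4806 and 2861. The median log2 difference of all probes moved from 0.03 to 0.14 in early Area X, from -0.03 to 0.08 in early HVC and from 0.05 to 0.15 in late RA. Between late and early singing it moved from -0.02 to -0.13 in HVC, from -0.02 to 0.09 in RA and from 0.02 to 0.14 in LMAN.

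With quantile normalization 92 of 96 named results and 20 of 22 counts were kept. Late against early LMAN went to 10 (4 higher, 6 lower) and the late test between regions to 225. In Area X the split went to 3686 and 3014 in the middle phase and 3611 and 3067 in the late phase, in middle HVC from 75 and 13 to 88 and 29. The median of all probes went from 0.02 to -0.09 and from 0.05 to -0.07 in the middle and late phases of Area X.

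With the authors' values, 81 of 96 named results were kept, and 15 of 22 counts. Early Area X went to 850, middle HVC to 48, late HVC to 149, middle RA to 30, early LMAN to 24, late against early LMAN to 337 and the early test between regions to 9. Here more probes were lower: 374 higher and 476 lower in early Area X, 3075 and 3228 in the middle phase and 2711 and 3150 in the late phase. The same held in late RA (34 and 128), middle LMAN (195 and 388), late LMAN (85 and 314), and late against early RA (100 and 415) and LMAN (5 and 332). Early RA had 29 and 6, middle RA 19 and 11 and middle HVC 30 and 18. The median of all probes between late and early LMAN went from 0.02 to -0.08.

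Without the filter on dim probes 89 of 96 named results were kept; early Area X went to 972, early, middle and late LMAN to 22, 504 and 161, more probes being tested. With the stricter filter all 79 named results still tested were kept, and late against early LMAN went to 22.

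Array weights kept 91 of 96 named results and raised 17 of 22 counts by more than 1.5 times. Area X went to 7425, 10247 and 11551 in the 3 phases, HVC to 177, 932 and 7520, RA to 124, 170 and 2583, and LMAN to 2203, 3907 and 1086. Late against early singing went to 1765 in Area X and 4563 in HVC, silent HVC to 5235, and the tests between regions to 1795 and 3311. In some of these fits the estimate of the weights stopped before it reached its tolerance, so the weighted counts are less certain than the others.

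Batch code as a random block kept 12 of 46 named results, and 12 of 12 counts fell. They were 73, 239 and 249 in Area X, 24, 0 and 10 in HVC, 0, 5 and 8 in RA, and 0, 9 and 9 in LMAN. Beside the limma counts of 0, 1019 probes in middle HVC, 752 in early RA and 1255 in early LMAN had an unadjusted p under 0.05. Scan date as a random block kept 13 of 46 named results; the counts were 116, 855 and 721 in Area X, 47, 21 and 36 in HVC, 0, 44 and 85 in RA, and 0, 25 and 38 in LMAN, with 1606 and 1417 at an unadjusted p under 0.05 beside the limma counts of 0 in early RA and LMAN. Since no batch code holds both silent and singing arrays, the batch block lowers the number of calls whatever their source. EGR1 early in RA, for example, went from 1.70 ± 0.33 to 1.79 ± 0.43 (SE) and lost its call as its error grew.

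With the replicate letter as a fixed block 17 of 46 named results were kept. Area X went to 375, 2095 and 1950, middle and late HVC to 42 and 109, RA to 3, 18 and 73, and early and middle LMAN to 28 and 365. Across singing times the letter goes partly with the batch code, so this block may take up part of the batch, which was not tested. Same-letter arrays had a median correlation of 0.04 in Area X, 0.25 in HVC, 0.21 in RA and -0.01 in LMAN, against -0.01, -0.08, -0.04 and 0.00 for other letters.

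Array design as a fixed block kept 33 of 42 named results; early Area X went to 650, and early and middle RA to 78 and 131. On the later design alone 57 of 83 were kept, with fewer samples. Area X went to 0, 2343 and 4321, middle and late HVC to 38 and 65, RA to 0, 29 and 46, and late against early singing to 9 in HVC and 76 in RA. Beside the limma counts of 0, 1874 probes in early Area X and 1854 in early RA had an unadjusted p under 0.05. The late test between regions went to 3837. Scan date as a fixed block kept 5 of 39 named results; it gave 4, 7 and 585 in Area X and 1938, 4335 and 4433 in RA, where most probes were then lower (424 higher and 1514 lower, 1169 and 3166, 1215 and 3218), and could not be fitted in HVC and LMAN.

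For late against early singing, the largest batch alone gave 132, 651, 101 and 152 in Area X, HVC, RA and LMAN, with fewer samples and mostly lower probes in the last 3. In LMAN that batch held a single late array, so the LMAN count and its direction are not read as a result. Without the batch block HVC went to 290, RA to 104 and LMAN to 77. With the replicate letter as a block in its place these counts went to 413, 157 and 68. With scan date as a random block beside batch code Area X went to 39, HVC to 1029 and RA to 35.

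In silent birds without the bird block 30 of 45 named results were kept, and the counts were 6503 for Area X, 1103 for HVC, 3312 for RA and 569 for LMAN. Against each of the other 3 regions singly 17 of 43 named results were kept, and 4783, 273, 1084 and 147 probes passed. The tests between regions gave 2 and 19 without the bird block, and 1 and 63 with batch code in its place.

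Leaving out 1 library at a time gave 399 to 3357 probes in early, 4039 to 6909 in middle and 4252 to 7066 in late Area X. It gave 57 to 81, 48 to 112 and 129 to 350 in HVC, 26 to 40, 29 to 83 and 119 to 412 in RA, and 9 to 495, 154 to 1782 and 73 to 673 in LMAN. Late against early singing gave 307 to 651 in Area X, 1632 to 3492 in HVC, 177 to 490 in RA and 0 to 27 in LMAN, where limma called 0 without 5 h d (3116 at an unadjusted p under 0.05). Silent birds gave 9567 to 12900 for Area X, 1800 to 3796 for HVC, 5771 to 8359 for RA and 982 to 2726 for LMAN, and the tests between regions 5 to 28 and 69 to 179. EGR1 early in Area X and HVC, EGR1 late against early in 3 regions, LARP5 in 3 phases and D1A late in Area X kept their calls in every refit. EGR1 passed as higher in silent HVC without Area X i (0.71, adjusted p = 0.0434) or LMAN f (0.72, adjusted p = 0.0423).

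Changes were recovered less often for dimmer probes. The simulated values used each probe's own spread, without a background floor and, in the comparisons with silence, without a batch effect. They therefore show neither a limit from background itself nor how batch affects the calls. In the simulated data for the comparisons with silence, changes of log2 2 were recovered for 557 of 642 probes well above background on at least 50% of arrays and for 93 of 150 dimmer ones, and changes of log2 1 for 246 of 669 and 11 of 135.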

Other observations

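No further test of a hypothesis was run for this part after the results were seen; the tests behind the values below are those of the planned comparisons.

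D1A, the dopamine receptor that rose in Area X, was also measurable outside it. In HVC its log2 level was 0.40 ± 0.53 (SD, n = 6) in silent birds and 1.28 ± 0.40 (SD, n = 5) at 5 h, and the late difference of 0.65 ± 0.29 (SE) did not pass (adjusted p = 0.302, higher in 12 of 15 arrays). In RA it was -0.70 ± 0.99 (SD, n = 7) in silent birds, and the middle difference of 1.03 ± 0.38 (SE) did not pass (adjusted p = 0.402, higher in 15 of 15 arrays). In LMAN the late difference was 0.15 ± 0.37 (SE, adjusted p = 0.885). ESR1, the oestrogen receptor that fell late in Area X, differed by -0.77 ± 0.34 (SE) late in HVC (adjusted p = 0.298, lower in 13 of 15 arrays) and by -0.71 ± 0.26 (SE) early in LMAN (adjusted p = 0.271, lower in 6 of 6), and neither passed.

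NKX2.2 differed by 0.88 in the middle phase of LMAN (adjusted p = 0.0722) and SCAMP1 by -0.69 in the late phase of LMAN (adjusted p = 0.0916), FNDC9 by 1.14 late in HVC (adjusted p = 0.21) and GPM6A by -0.98 late in RA (adjusted p = 0.163). None of these passed.

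Probes without a gene name were shared beyond the early phase. In Area X, HVC and RA together 22 probes were called higher in the middle phase and 35 late (0.0129 and 0.0988 for independent lists), and 17 were called lower late (0.0128). In all 4 regions 15 were higher in the middle phase and 15 late, and 9 were lower late. Area X and LMAN shared 405 probes higher in the middle phase (59.9 for independent lists). None of these carried a gene name, and since the regions share birds and batches the overlap is not taken as a shared response.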
